A study of Bos taurus with 18 samples.

How the data were processed

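RNA of bovine blastocysts was measured on 18 1-colour Agilent arrays of the EmbryoGENE bovine design, 3 arrays in each of 6 groups. Per the labels, RNA was extracted with the PicoPure kit, amplified in 2 rounds with the RiboAmp HSPlus kit and labelled with Cy3. Per the file headers, each scan at 532 nm held the median foreground and median local background of each spot in units of intensity, neither corrected nor scaled, and a mark for spots set aside. The deposited value table of the authors was in log2 units: its values were the log2 of median foreground minus median background, quantile normalized over the 18 arrays, as a comparison with the scans showed, and empty at spots set aside. Per the labels, 9 of the 18 arrays were processed with R 3.2.4 and limma 3.28.5; the labels of the other 9 name no processing. Slides were known from the file names alone: 4 slides held 4 of these arrays each and the remaining slide 2. Slide 1 held replicates 1 and 2 of day6 and day6+2, slide 2 those of day8 and day7+1, slide 3 those of day6+1 and day7, slide 4 replicate 3 of day6, day6+2, day6+1 and day7+1, and slide 5 replicate 3 of day8 and day7.

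Of 43794 probes, 21790 were paired with 1 gene symbol, 0 with several and 22004 with none. The symbols are those of the array's annotation, some of them older names: IFNT is listed as an older symbol of IFNT2 in the reference gene table of ARS-UCD2.0, and GATA6, a marker fixed beforehand, was not on the array's table and is not analysed here. Foreground and background were corrected with normexp (offset 50) and quantile normalized in limma 3.58.1 under R 4.3.3. Spots set aside were treated as missing, 187 of them in the features tested, and 40 spots over all arrays were at the scanner's limit. A probe was kept if it lay above the 95th percentile of the negative control spots on 3 or more of the 18 arrays, which left 39991 probes (91.3%). Each gene was represented by its brightest probe over all arrays, chosen without regard to group, as 3666 genes had more than 1 probe kept; probes with no symbol stayed as features of their own. The negative controls had a median of 83 to 189 intensity units and the local background one of 14 to 21. The number of arrays limits the precision. The column medians of the authors' table lay at 7.76 to 7.77 log2 units.

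The 9 pairwise comparisons and the interaction came from 1 linear model in limma with a mean for each of the 6 groups over all 18 arrays. The 3 trends came from a model with the day of formation and the days of extra culture as numbers. Moderated variances and Benjamini-Hochberg adjustment over all 34269 features were used in each comparison, with a threshold of 0.05. The 31 gene lists, written before the data were examined, were tested with camera in limma with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 403 pairs of list and comparison; camera with an estimated correlation and fry were run beside it. In no pair under the threshold did the mean or the median of a list differ in sign from its test. The lists covered trophectoderm, trophoblast secretory, epiblast and pluripotency, hypoblast, blastocoel junction and transport, attachment, cytoskeleton, mitotic cell cycle, DNA replication, chromatin modifiers, DNA methylation and imprinted, X-linked and Y-linked genes, oocyte, cumulus and granulosa, and fibroblast and kidney epithelial genes. They also covered growth factors, interferon-stimulated genes, ribosomal proteins, proteasome, heat shock, endoplasmic reticulum stress, oxidative stress and metallothionein, hypoxia, p53 and apoptosis, glycolysis, the citrate cycle, oxidative phosphorylation, lipid metabolism, cholesterol synthesis, and amino acid and one-carbon genes. The genes named in the text were fixed by a rule before the data were examined: in each comparison the 5 largest rises and 5 largest falls among genes past the threshold whose replicates did not overlap (for trends and the interaction, past the threshold), up to 4 members with the smallest p of each list past the threshold, the 3 genes with the smallest p where fewer than 5 passed in a direction, and 20 fixed markers. Of 751 such values, 234 passed. A fold is given as a bound where a gene was not above the negative controls in a group.

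The replicate numbers were checked for pairing: only in day7 against day6+1 did replicates with the same number correlate by over 0.1 in each of the 3 pairs after the group means were removed (r = 0.45, 0.106 and 0.235). A fit with the replicate number as a block gave 0 features there, as without the block. The alternatives planned before the data were examined were another background correction and scaling (background-subtracted signal scaled to the 75th percentile), centring on the median, no filter on dim probes, the mean of a gene's probes, the authors' table, the slide as a fixed or random block, the replicate number as a block, another variance model, only the 6 arrays compared, the arrays of a shared slide, each array left out in turn, and the 2 other list tests. Another 3, chosen after the data had been seen, were background from the negative controls, day6+1 replicate 1 and day7 replicate 1 both out, and the co-varying features out (r with the first component over 0.8 or under -0.8). The no-filter alternative kept dim probes too and tested 37233 features, still with 1 probe for each gene.

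The fits were tested on simulated data with the spread of the real features and 200 of 34269 features changed, 50 at each log2 size. Over the 9 pairwise comparisons 0% to 8% of the changed features were recovered at a size of 0.5, 40% to 60% at 1, 86% to 96% at 1.5 and 94% to 100% at 2. The interaction recovered 0%, 16%, 62% and 84% at these sizes, and the 3 trends recovered 66% to 80% at 0.5, 96% to 98% at 1, 98% at 1.5 and 100% at 2 per day. Unchanged features called numbered 3 to 13 per comparison, and with no feature changed limma called 0 in each of the 13 comparisons. In a simulated list test of day8 against day6, a shift of 0.5 in the 26 trophectoderm members gave an adjusted p of 1.07e-15 and 0 of the other lists passed. All simulated features varied independently, with no correlation between genes and no effect of slides or single arrays. The simulations therefore do not measure how often the fits or the list tests make false calls on the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe sequences and a reference genome are not used here, so which probes bind several transcripts was not examined.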

Results

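The 18 arrays measured RNA from bovine blastocysts made by in vitro fertilisation with semen of a single bull and grown on VERO cells, a monkey kidney cell line used as a co-culture. The design separated the day on which the blastocoel, the fluid cavity of the blastocyst, had formed from the time spent in culture afterwards. Blastocysts collected when the cavity formed made the groups day6, day7 and day8. Blastocysts kept in culture after it formed made day6+1 and day7+1, with 1 extra day, and day6+2, with 2 extra days. Each group held 3 arrays, labelled as biological replicates; the number of embryos behind an array and whether the replicates came from separate cultures are not given, so the p-values measure the spread between samples. The median raw signal of an array ran from 143 to 281 intensity units over a local background of 14 to 21, and 72.0% to 81.1% of the 43794 probes lay above the negative control spots. The tests covered 34269 features, of which 14543 were genes and 19726 were probes with no gene symbol. The number of arrays limits the precision of every value below. Differences are on the log2 scale, and ± after a difference is the standard error of the fit with n = 3 arrays in each group.

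Pearson correlations between arrays over all features ran from 0.953 to 0.982, and within the groups from 0.963 in day7 to 0.981 in day8. The first principal component held 18.2% of the variance, the next 15.6% and the one after 8.58%. The first component set the 3 day8 arrays, day6+1 replicate 1 and day7 replicate 1 apart from the other 13. It followed a set of 369 features with a correlation over 0.8 with it, 171 of them genes and 198 unnamed probes. The mean of this set was 10.82, 10.77 and 10.33 on the day8 arrays, 10.86 on day6+1 replicate 1 and 11.57 on day7 replicate 1, and 8.45 to 9.66 on the remaining arrays. The other probes of the set's genes did not follow it: 97 other probes of 63 genes differed by a median of 0.04 between the same 5 and 13 arrays, against 2.17 for the set's own probes of those genes. The set is called the co-varying set below, and its genes are marked by their correlation r with the first component. Another 80 features, GATA4 and PLCH1 among them, had r under -0.8.

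**Figure D1:**
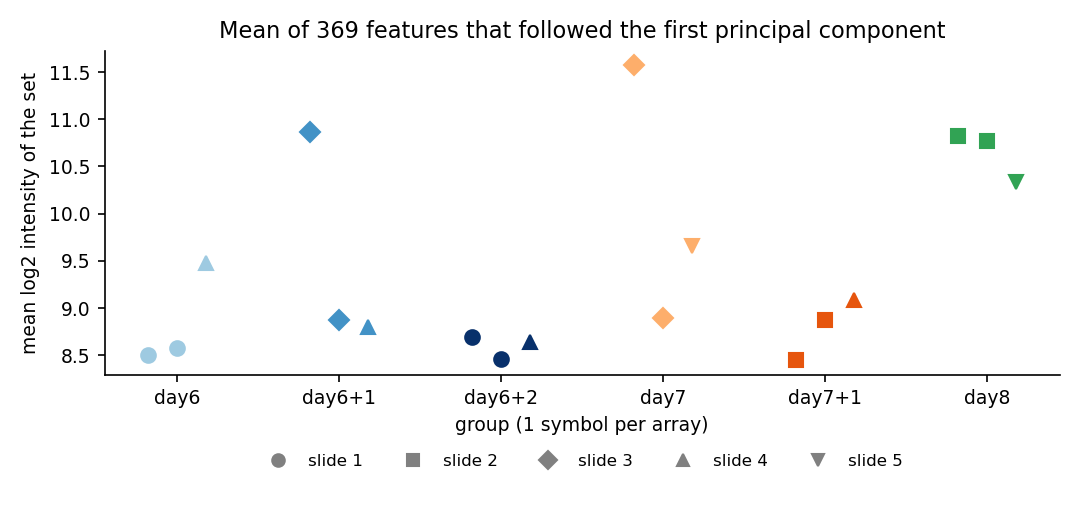
Mean log2 signal of the 369 features of the co-varying set on each of the 18 arrays, grouped by day of blastocoel formation and extra culture. The 3 day8 arrays, day6+1 replicate 1 and day7 replicate 1 lie between 10.33 and 11.57 and the other arrays between 8.45 and 9.66.

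The comparison of day6+2 with day6 asked what 2 extra days of culture changed in blastocysts whose cavity had formed on day 6. The trophoblast is the outer layer that later makes the placenta. Its secretory list had the highest mean of the 31 gene lists examined, but 11 of its 20 genes did not pass and the list did not pass with an estimated correlation (adjusted p = 0.125). IFNT, the interferon by which the ruminant trophoblast signals pregnancy, rose by 3.56 ± 0.42 (adjusted p = 3.57e-05), from a level of 11.74 ± 0.42 (SD, n = 3) in day6 to 15.29 ± 0.35 in day6+2. The steroid-making enzymes HSD3B1 and CYP11A1 rose by 3.63 ± 0.39 and 3.13 ± 0.45. The pregnancy-associated glycoprotein PAG11 was not above background in day6 and was at least 8.04-fold higher in day6+2. Among stress genes, the heme oxygenase HMOX1 rose by 3.77 ± 0.41, the sulfiredoxin SRXN1 by 2.09 ± 0.23 and the superoxide dismutase SOD1 by 1.45 ± 0.25. Of the glycolytic enzymes, TPI1, ENO1 and LDHA rose by 3.41 ± 0.37, 1.64 ± 0.27 and 1.07 ± 0.24. Among transcription factors of the early embryo, SPIC fell by 2.30 ± 0.24, ARGFX by 2.13 ± 0.34, KLF4 by 1.71 ± 0.27 and POU5F1 by 1.09 ± 0.26, while NANOG, of the same list, rose by 2.50 ± 0.35.

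The 5 largest rises among named genes were those of LOC513329 (4.59 ± 0.64) and LOC783399 (4.52 ± 0.54), which the array names only as loci, the heme-binding protein HEBP2 (3.83 ± 0.41), HMOX1 and PAGE4 (3.75 ± 0.46). The 5 largest falls were those of the ubiquitin ligase TRIM63, which fell by 3.57 ± 0.38 (adjusted p = 1.44e-05), the lyase AGXT2L1, which fell by 3.09 ± 0.49, the claudin CLDN10 by 2.79 ± 0.34, the haemoglobin gene HBG by 2.71 ± 0.64 and the glycine decarboxylase GLDC by 2.44 ± 0.47. The trophectoderm list members TFAP2A, KRT19, SFN and CDX2 rose by 2.79 ± 0.32, 1.75 ± 0.30, 1.70 ± 0.24 and 0.92 ± 0.21. The desmosome proteins DSP and DSC2 rose by 1.68 ± 0.21 and 1.68 ± 0.30. The prostaglandin synthase PTGS2 rose by 2.29 ± 0.41, and the methyltransferase DNMT3B by 0.90 ± 0.24 (r = -0.74). The quinone reductase NQO1, not above background in day6, was at least 2.07-fold higher. The receptor gene PDGFRA fell by 0.90 ± 0.21, the junction protein F11R by 0.94 ± 0.16, the mitotic kinesin KIF20A by 1.06 ± 0.22 and the histone methyltransferase SETDB1 by 0.92 ± 0.20; KRT18 did not pass (0.58 ± 0.18). The other probes of some of these genes changed less: they differed by 0.10 to 0.70 for TFAP2A, -0.01 to 0.67 for HEBP2, 0.31 to 1.94 for PTGS2 and -0.52 to 0.24 for PDGFRA. They differed by 0.52 for SRXN1, 0.45 for PAG11, 0.29 for ENO1, -0.75 for SPIC and -0.21 for DSC2.

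Over the gene lists, the oxidative stress and metallothionein list rose by a mean of 0.61 (adjusted p = 3.54e-11, 0.0117 with an estimated correlation). Of its 33 genes 10 rose, 0 fell and 23 did not pass (17 rose and 1 fell adjusted over the list alone). The trophoblast secretory list rose by a mean of 1.35 (adjusted p = 3.73e-09, 0.125 with an estimated correlation), 1.45 within slide 1 and 1.15 within slide 4. Of its 20 genes 9 rose, 0 fell and 11 did not pass (10 rose and 0 fell adjusted over the list alone). The trophectoderm list rose by 0.47 (adjusted p = 2.98e-05, 0.0321 with an estimated correlation), and of its 26 genes 7 rose, 1 fell and 18 did not pass (9 rose and 1 fell adjusted over the list alone). The chromatin modifier list fell by 0.28 (adjusted p = 7.41e-05, 0.0321 with an estimated correlation), and of its 32 genes 0 rose, 4 fell and 28 did not pass (0 rose and 7 fell adjusted over the list alone). The other lists under the threshold were not under it with an estimated correlation: endoplasmic reticulum stress rose by 0.54 (5 rose, 0 fell and 20 did not pass (9 rose and 0 fell adjusted over the list alone)), and glycolysis by 0.45 (5 rose, 1 fell and 17 did not pass (10 rose and 2 fell adjusted over the list alone)). Oxidative phosphorylation fell by 0.29 (0 rose, 2 fell and 51 did not pass (0 rose and 8 fell adjusted over the list alone)). The adjusted p with an estimated correlation was 0.180, 0.125 and 0.0614 in these 3 lists. It was 0.119 for the mitotic cell cycle list, which fell by 0.30, and 0.125 for the DNA replication list, which fell by 0.24. It was 0.125 for the epiblast list, which fell by 0.19 (4 rose, 6 fell and 17 did not pass (5 rose and 8 fell adjusted over the list alone)), and 0.370 for the cholesterol synthesis list, which rose by 0.29. It was 0.216, 0.279 and 0.125 for the cytoskeleton, junction and transport, and p53 lists, which rose by 0.25, 0.20 and 0.22.

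Of the 34269 features, 1229 passed in limma's fit, 790 of them higher and 439 lower in day6+2. Of all features, 18.1% had groups that did not overlap, where chance gives 10%. With each array centred on its median the split was 930 and 211, and the named falls of POU5F1, PDGFRA, SETDB1, CCNB1, EZH2, GINS1, HDAC8, NDUFB6, SUV39H1 and UBE2C did not pass. Background subtraction with scaling to the 75th percentile shifted the median of all features by -0.10. PDGFRA, EZH2 and NDUFB6 did not pass with the mean of a gene's probes. With the slide as a block 1533 features passed. Slides 1 and 4 each held arrays of both groups, and within slide 1 alone 1226 passed. The count was 695 without day6 replicate 2 and 703 without day6+2 replicate 2. Of 55 named genes that passed, 35 passed whichever array was left out, IFNT, HSD3B1, CYP11A1, PAG11, HMOX1, SRXN1, TPI1, TFAP2A, NANOG, KLF4, ARGFX, SPIC and TRIM63 among them.

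**Figure D2:**
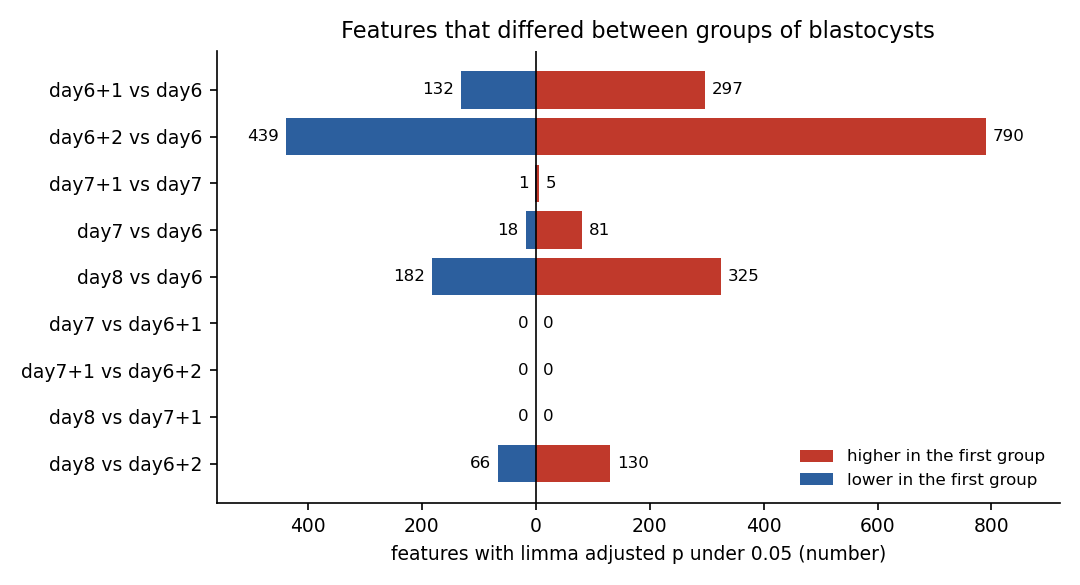
Number of features with an adjusted p under 0.05 in limma's fit, drawn to the right where higher and to the left where lower in the first group, in each of the 9 pairwise comparisons of 34269 features. The bars are longest for day6+2 against day6 (790 and 439) and 0 for day8 against day7+1, day7+1 against day6+2 and day7 against day6+1.

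**Figure D3:**
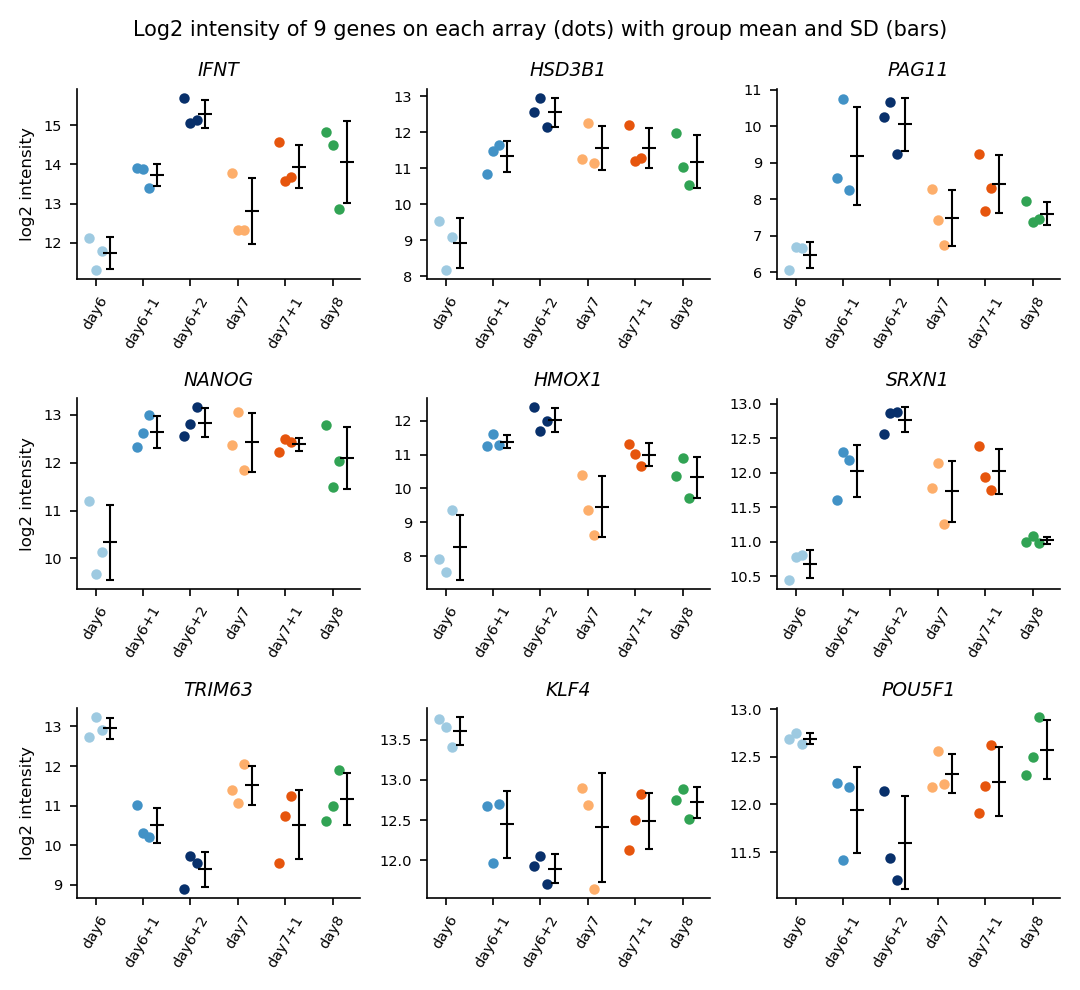
Log2 intensity of 9 genes on each array, by group; each dot is an array and each bar the mean and SD of 3 arrays. IFNT runs from a mean of 11.74 in day6 to 15.29 in day6+2 and TRIM63 from 12.96 to 9.39.

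The comparison of day6+1 with day6 asked what the first extra day changed. Of the 31 lists, the trophectoderm and oxidative stress lists rose and passed with both correlations. IFNT rose by 1.99 ± 0.42 (adjusted p = 0.0183), HSD3B1 by 2.40 ± 0.39, CYP11A1 by 2.83 ± 0.45, and PAG11 was at least 4.44-fold higher than in day6, where it was not above background. HMOX1 rose by 3.12 ± 0.41 (adjusted p = 3.53e-04), SRXN1 by 1.35 ± 0.23 and the glutathione synthesis gene GCLM by 1.16 ± 0.25. The desaturases FADS2 and SCD rose by 1.64 ± 0.21 and 1.42 ± 0.28, and the sterol synthesis enzymes HMGCS1, PMVK and CYP51A1 by 1.45 ± 0.25, 1.43 ± 0.23 and 1.29 ± 0.28. The trophectoderm list members TFAP2A, KRT19, SFN and CDX2 rose by 2.56 ± 0.32, 1.71 ± 0.30, 1.42 ± 0.24 and 0.84 ± 0.21, the desmosome protein DSP by 1.49 ± 0.21, NANOG by 2.31 ± 0.35 and PTGS2 by 1.89 ± 0.41.

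The 5 largest rises were those of LOC783399 (3.76 ± 0.54), LOC513329 (9.75-fold), HMOX1, HEBP2 (2.97 ± 0.41) and CYP11A1. The 5 largest falls were those of AGXT2L1, which fell by 2.68 ± 0.49, TRIM63 by 2.45 ± 0.38, GLDC by 2.05 ± 0.47, ARGFX by 2.01 ± 0.34 and the collagen gene COL9A2 by 2.01 ± 0.34. Other probes differed by 0.20 to 0.71 for TFAP2A, 0.37 to 0.76 for HEBP2, -0.12 to 1.09 for HMGCS1, 0.43 to 1.52 for PTGS2. They differed by 0.14 for PMVK, 0.24 for SRXN1 and 0.49 for PAG11. The cholesterol synthesis list rose by a mean of 0.61 (adjusted p = 2.25e-12, 0.0709 with an estimated correlation, mean 0.67 within slide 4). Of its 21 genes 5 rose, 0 fell and 16 did not pass (8 rose and 0 fell adjusted over the list alone). The trophectoderm list rose by 0.43 (adjusted p = 8.34e-06, 0.0250 with an estimated correlation), and the oxidative stress list by 0.41 (adjusted p = 1.60e-07, 0.0321 with an estimated correlation). Of their 26 and 33 genes 4 and 4 rose, 0 fell, and 7 and 8 rose adjusted over the list alone. Within slide 4 these 2 lists differed by means of 0.43 and 0.24. The trophoblast secretory list rose by 1.02 (6 rose, 0 fell and 14 did not pass (9 rose and 1 fell adjusted over the list alone)) and the lipid list by 0.26 (4 rose, 1 fell and 30 did not pass (7 rose and 3 fell adjusted over the list alone)), with an adjusted p = 0.145 and 0.0596 with an estimated correlation. Endoplasmic reticulum stress rose by 0.39 and junction and transport by 0.21, while oxidative phosphorylation fell by 0.23 and mitotic cell cycle by 0.27. None of these 4 passed with an estimated correlation (adjusted p = 0.250, 0.206, 0.0733 and 0.102). DNA replication fell by 0.14 and chromatin modifiers by 0.15; with each array centred on its median these means were 0.02 and 0.0025. Neither passed with an estimated correlation (adjusted p = 0.277 and 0.125).

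The test called 429 features in limma, 297 higher and 132 lower in day6+1. Of all features, 15.2% had groups that did not overlap, where chance gives 10%. With each array centred on its median the split was 391 and 50. Background subtraction with scaling to the 75th percentile shifted the median of all features by -0.13. Only slide 4 held arrays of both groups, 1 of each, and with the slide as a block 29 passed, PMVK, PTGS2, COL9A2 and TRIM63 among them. The count was 230 without day6 replicate 1, 129 without day6 replicate 2, 123 without day6+1 replicate 2 and 271 without day6+1 replicate 3. Of 33 named genes that passed, 18 passed whichever array was left out, HMOX1, TFAP2A, CYP11A1, HSD3B1, FADS2, HMGCS1, PMVK, DSP and NANOG among them, and IFNT was not. With day6+1 replicate 1 and day7 replicate 1 both out, CDX2 did not pass, and with the mean of a gene's probes HEBP2, PMVK, PTGS2 and SRXN1 did not.

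The comparison of day7+1 with day7 asked what 1 extra day changed in blastocysts whose cavity had formed on day 7. Few features passed: 6 of 34269 in limma's fit, 5 higher and 1 lower in day7+1, against 2451 with an unadjusted p under 0.05, and 10.6% of all features had groups that did not overlap, where chance gives 10%. The gene among the 6 was DMBT1, a secreted scavenger receptor protein, which fell by 1.87 ± 0.31 (adjusted p = 0.0387). The smallest p-values of named genes after it were those of CPEB4 (1.33 ± 0.24) and LOC512005 (-1.76 ± 0.31), both with an adjusted p = 0.0547. HMOX1 differed by 1.53 ± 0.41 and TXNIP by -1.87 ± 0.62 and neither passed. The count was 0 with the slide as a block, where no slide held arrays of both groups, 0 with each array centred on its median, and 0 without day7 replicate 3, day7+1 replicate 1 or day7+1 replicate 2. The endoplasmic reticulum stress list rose by a mean of 0.26 (adjusted p = 0.00668, 0.501 with an estimated correlation), which the slide block changed to -0.05. Oxidative stress rose by 0.15, DNA replication fell by 0.13 and oxidative phosphorylation by 0.11 (adjusted p = 0.194, 0.214 and 0.331 with an estimated correlation).

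The interaction asked whether the extra day acted differently after day 7 than after day 6. The gene CREB3L2, a transcription factor of the secretory pathway, passed: its change over the extra day was higher after day 7 than after day 6 by 2.30 ± 0.35 (adjusted p = 0.0334). Of 34269 features 2 passed in limma, CREB3L2 and an unnamed probe, against 2307 with an unadjusted p under 0.05. The trophectoderm list changed less over the extra day after day 7 than after day 6, with a mean difference of -0.38 (adjusted p = 2.52e-04, 0.0428 with an estimated correlation). The sterol list had a mean difference of -0.54 (adjusted p = 7.53e-08, 0.146 with an estimated correlation) and the trophoblast secretory list one of -0.84 (adjusted p = 1.22e-04, 0.276 with an estimated correlation). The single genes of these lists did not pass: HSD3B1 differed by -2.39 ± 0.55 and PMVK by -1.56 ± 0.32. NANOG, of the epiblast list, differed by -2.36 ± 0.50 (adjusted p = 0.0990) and did not pass either. The count of features was 0 with the slide as a block and 0 with day6+1 replicate 1 and day7 replicate 1 both out. It was 4 without day6 replicate 1, 1 without day6 replicate 2, 5 without day6 replicate 3, 1 without day6+1 replicate 3, 1 without day7 replicate 2, 70 without day7 replicate 3 and 1 without day7+1 replicate 3, and 0 without any other of the 12 arrays. Background subtraction with scaling to the 75th percentile shifted the median of all features by 0.16 in the interaction.

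The linear fit over all 18 arrays asked what each extra day of culture changed at equal day of formation. Per day of extra culture IFNT rose by 1.65 ± 0.20 (adjusted p = 4.70e-05), HSD3B1 by 1.45 ± 0.24, HMOX1 by 1.81 ± 0.22 and TFAP2A by 1.34 ± 0.19. The locus LOC781778 rose by 1.73 ± 0.23, LOC513329 by 2.09 ± 0.30, LOC783399 by 2.04 ± 0.29 and PAGE4 by 1.70 ± 0.22. PAG11 rose too, with no size given, as it was not above background in day6. TRIM63 fell by 1.63 ± 0.19 per day (adjusted p = 4.07e-05), SPIC by 1.04 ± 0.12, the inositol kinase ITPKA by 1.11 ± 0.15, DPPA3 by 0.56 ± 0.11, EZH2 by 0.36 ± 0.08 and POU5F1 by 0.45 ± 0.12. NANOG rose by 0.99 ± 0.22 and the co-receptor TDGF1 by 1.10 ± 0.23. The fit gave each gene a single slope for all days of formation. A slope thus does not show that a gene changed in day7+1 against day7 as it did in day6+1 against day6. For HSD3B1 and NANOG the interaction above was negative and about as large as their rise in day6+1 against day6, though it did not pass. The oxidative stress list rose by 0.27 per day (adjusted p = 1.62e-10, 0.0117 with an estimated correlation), and of its 33 genes 10 rose, 0 fell and 23 did not pass (17 rose and 1 fell adjusted over the list alone). The other lists that passed did not pass with an estimated correlation: the trophoblast secretory list rose by 0.58 (9 rose, 0 fell and 11 did not pass (10 rose and 0 fell adjusted over the list alone)), endoplasmic reticulum stress by 0.27, trophectoderm by 0.20, glycolysis by 0.18, sterol synthesis by 0.13, p53 by 0.11 and cytoskeleton by 0.11. Oxidative phosphorylation fell by 0.14, DNA replication by 0.12, mitotic cell cycle by 0.13, chromatin modifiers by 0.11 and epiblast by 0.09. The lowest adjusted p among these lists was 0.0614 with an estimated correlation. Per day of extra culture 1288 features passed in limma's fit, 831 higher and 457 lower per day, and 1477 with the slide as a block. Centred on the median the split was 793 and 237, and EZH2 and POU5F1 did not pass. EZH2 did not pass with the mean of a gene's probes either. The count was 814 without day6 replicate 1, 672 without day6 replicate 2 and 806 without day6+2 replicate 2, and 39 of the 56 named genes that passed did so whichever array was left out.

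The comparison of day8 with day6 asked how late blastocysts differed from early ones when both were collected as the cavity formed. Day8 was also the older group, so later formation and greater age cannot be told apart in it. The urokinase protease PLAU rose by 2.87 ± 0.31 (adjusted p = 2.79e-04), CYP11A1 by 2.54 ± 0.45 and the trophoblast Kunitz domain protein TKDP1 by 2.47 ± 0.57. IFNT rose by 2.32 ± 0.42, HSD3B1 by 2.25 ± 0.39 and NANOG by 1.77 ± 0.35. The endoplasmic reticulum chaperones HSP90B1 and HSPA5 rose by 1.63 ± 0.30 and 1.52 ± 0.31, and TFAP2A and KRT19 by 1.81 ± 0.32 and 1.66 ± 0.30. GATA4, a transcription factor of the primitive endoderm, fell by 2.47 ± 0.55 (adjusted p = 0.0270, r = -0.81). The respiratory chain genes COX8A and UQCRQ fell by 0.81 ± 0.19 and 0.75 ± 0.18 and the replication gene ORC1L by 0.84 ± 0.19. Of the 5 largest rises, ARSI (3.43 ± 0.84, r = 0.97), ROBO2 (3.29 ± 0.83, r = 0.97) and ZCCHC12 (3.00 ± 0.68, r = 0.96) belonged to the co-varying set, and the second probe of ROBO2 differed by 0.30; LOC783399 (3.42 ± 0.54) and LOC513329 (2.99 ± 0.64) did not belong to it. The 5 largest falls were those of PLCH1, which fell by 3.34 ± 0.69 (r = -0.81), LOC613677 by 2.94 ± 0.64 (r = -0.76), ARPP21 by 2.84 ± 0.61 (r = -0.79), DHODH, which fell by 2.61 ± 0.63 (r = -0.74) and MIR296 by 2.54 ± 0.60 (r = -0.80). The other probes of TFAP2A differed by 0.08 to 0.40, that of HSP90B1 by 0.39 and those of ARPP21 by -0.10 to -0.01.

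The oxidative phosphorylation list fell by a mean of 0.34 (adjusted p = 6.02e-11, 0.0321 with an estimated correlation) and fell by 0.16 with the slide as a block (adjusted p = 0.0610). Of its 53 genes 0 rose, 2 fell and 51 did not pass (0 rose and 13 fell adjusted over the list alone). The p53 list rose by 0.26 (adjusted p = 0.00314, 0.0439 with an estimated correlation) with 0 single genes past the threshold and 5 adjusted over the list alone. The rest did not pass with an estimated correlation. Endoplasmic reticulum stress rose by 0.56 (4 rose, 0 fell and 21 did not pass (10 rose and 0 fell adjusted over the list alone); adjusted p = 0.154 with an estimated correlation), the trophoblast secretory list by 0.73 (5 rose, 0 fell and 15 did not pass (6 rose and 1 fell adjusted over the list alone); 0.365), trophectoderm by 0.33 (0.0510), attachment by 0.35 (0.0614), sterol synthesis by 0.31 (0.327), X-linked genes by 0.24 (0.194) and cytoskeleton by 0.22 (0.239). Mitotic cell cycle fell by 0.27 (0.125), DNA replication by 0.26 (0.119), chromatin modifiers by 0.18 (0.119) and the citrate cycle by 0.20 (0.134).

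Between day8 and day6 507 features passed in limma's fit, 325 higher and 182 lower in day8, and 64 of the rises were in the co-varying set. Of these, 208 rises and 58 falls were also called in day6+2 against day6, which shares the day6 arrays. Independent lists would share 7.49 and 2.33. The shared day6 arrays by themselves raise the overlap above these figures, by an amount that was not tested. Of all features, 17.5% had groups that did not overlap, where chance gives 10%. Centred on the median the split was 359 and 65, and COX8A, UQCRQ, ORC1L, ARSI and ROBO2 did not pass. HSP90B1, TFAP2A, ARSI, ROBO2 and DHODH did not pass with the mean of a gene's probes. No slide held arrays of both groups, and with the slide as a block 1 feature passed, PLAU, which rose by 3.33 in that fit. The count was 156 without day6 replicate 1, 42 without day6 replicate 2, 86 without day8 replicate 1 and 93 without day8 replicate 2, and 2 of the 31 named genes that passed, PLAU and LOC783399, did so whichever array was left out.

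The comparison of day7 with day6 asked the same of blastocysts that formed their cavity 1 day later and were older by that day. PLAU rose by 2.36 ± 0.31 (adjusted p = 0.00174), HSD3B1 by 2.63 ± 0.39, CYP11A1 by 2.35 ± 0.45, NANOG by 2.09 ± 0.35, KRT19 by 1.65 ± 0.30, TFAP2A by 1.59 ± 0.32, SFN by 1.54 ± 0.24, the desaturase FADS2 by 1.30 ± 0.21 and TPI1 by 1.92 ± 0.37. Among the largest rises were also the adaptor protein STAP2 (2.53 ± 0.36), whose other probes differed by -0.04 to 0.74, the myosin light chain MYL7 (2.71 ± 0.56), HEBP2 (2.49 ± 0.41) and LOC783399 (2.50 ± 0.54). The other probes of TFAP2A differed by -0.09 to 0.28 and those of HEBP2 by 0.29 to 0.63. The 5 largest falls were those of ARGFX, which fell by 1.74 ± 0.34 (adjusted p = 0.0259), KCTD1 by 1.27 ± 0.27, KLHL24 by 1.26 ± 0.22, CHORDC1 by 1.24 ± 0.26 and the potassium channel KCNT1 by 1.24 ± 0.24. The trophectoderm list rose by a mean of 0.32 (adjusted p = 3.99e-04, 0.0428 with an estimated correlation; 3 rose, 0 fell and 23 did not pass (5 rose and 0 fell adjusted over the list alone)). The lipid list rose by 0.24 (adjusted p = 0.00257, 0.0439 with an estimated correlation). The chromatin modifier list fell by 0.21 (adjusted p = 5.69e-04, 0.0428 with an estimated correlation), with the slide as a block by 0.33. The others did not pass with an estimated correlation: mitotic cell cycle fell by 0.31 (adjusted p = 0.0614 with an estimated correlation), DNA replication by 0.17 (0.216), oxidative phosphorylation by 0.17 (0.146) and the amino acid and one-carbon list by 0.14 (0.206). The trophoblast secretory list rose by 0.76 (0.216), sterol synthesis by 0.39 (0.186), endoplasmic reticulum stress by 0.25 (0.387), oxidative stress by 0.17 (0.213), attachment by 0.23 (0.145) and glycolysis by 0.24 (0.276). The slide block gave an oxidative phosphorylation mean of 0.00250 (adjusted p = 0.964). The test in limma called 99 features, 81 higher and 18 lower in day7. Of these, 66 rises and 11 falls were also called in day6+2 against day6, with the same day6 arrays. Independent lists would share 1.87 and 0.231, and here too the shared day6 arrays by themselves raise the overlap. Of all features, 12.9% had groups that did not overlap, where chance gives 10%. No slide held arrays of both groups, and with the slide as a block 4 passed, PLAU among them. Centred on the median the split was 83 and 5, and KCTD1, CHORDC1, KCNT1 and LOC783399 did not pass. With day6+1 replicate 1 and day7 replicate 1 both out, these 4 genes, KLHL24, KRT19, MYL7 and TPI1 did not pass. TFAP2A, HEBP2, LOC783399, STAP2, KCTD1 and CHORDC1 did not pass with the mean of a gene's probes. The count was 49 without day6 replicate 1, 10 without day6 replicate 2, 42 without day7 replicate 1, 57 without day7 replicate 2 and 154 without day7 replicate 3, and PLAU and STAP2 passed whichever array was left out.

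The linear fit also asked what each later day of cavity formation changed at equal extra culture. At equal extra culture, later formation was also greater age. Per later day PLAU rose by 1.25 ± 0.21 (adjusted p = 0.0151), IFNT by 0.97 ± 0.20, the muscle stress protein ANKRD1 by 0.95 ± 0.12 (adjusted p = 0.00136), the sulfhydryl oxidase QSOX1 by 0.90 ± 0.18, and NUCB2 by 0.88 ± 0.19. The endoplasmic reticulum genes HSPA5, HSP90B1 and SEL1L rose by 0.71 ± 0.14, 0.70 ± 0.14 and 0.64 ± 0.12. ITPKA fell by 0.76 ± 0.15 (adjusted p = 0.0337), the protease inhibitors SERPINB4 and SERPINA5 by 0.60 ± 0.12 and 0.55 ± 0.11, the mannose phosphate mutase PMM1 by 0.56 ± 0.11 and the zinc transporter SLC30A2 by 0.53 ± 0.11. The oxidative phosphorylation list fell by 0.15 per later day (adjusted p = 3.54e-11, 0.0344 with an estimated correlation; 0 rose, 0 fell and 53 did not pass (0 rose and 8 fell adjusted over the list alone)) and by 0.09 with the slide as a block. DNA replication fell by 0.14 and by 0.08 with the slide as a block, and attachment rose by 0.15 and p53 by 0.11 (adjusted p = 0.0428, 0.0428 and 0.0439 with an estimated correlation). Endoplasmic reticulum stress rose by 0.25 (3 rose, 0 fell and 22 did not pass (9 rose and 0 fell adjusted over the list alone); adjusted p = 0.119 with an estimated correlation), the trophoblast secretory list by 0.28 (0.438), trophectoderm by 0.12 (0.194), X-linked genes by 0.11 (0.213) and cytoskeleton by 0.10 (0.214). Mitotic cell cycle fell by 0.13 (0.125), chromatin modifiers by 0.08 (0.163) and the citrate cycle by 0.09 (0.102). In limma's fit 86 features passed, 61 higher and 25 lower per later day; centred on the median the split was 15 and 1, and of the genes named here PLAU, ANKRD1 and SEL1L alone passed. HSP90B1, SEL1L, NUCB2, PMM1 and SLC30A2 did not pass with the mean of a gene's probes. Of the 61 rises 53, and of the 25 falls 16, were also called per day of extra culture, on the same arrays. Independent lists would share 1.48 and 0.333. Both slopes come from the same fit, in which groups of later formation had fewer extra days, so their errors are correlated. Part of the overlap is thus given by the design, and the excess is not read as a shared response. With the slide as a block 0 passed in limma's fit, where 3112 had an unadjusted p under 0.05. The count was 6 without day6 replicate 1, 1 without day6 replicate 2, 11 without day6 replicate 3, 1 without day8 replicate 1, 6 without day8 replicate 2, 180 without day8 replicate 3, 218 without day6+1 replicate 2 and 18 without day7+1 replicate 1; of the 13 named genes that passed, ANKRD1 alone passed whichever array was left out.

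The comparison of day8 with day6+2 set blastocysts of equal age side by side, with the cavity formed late in day8 and early in day6+2. SRXN1 fell by 1.75 ± 0.23 (adjusted p = 0.00324), the glutathione peroxidase GPX4 by 0.96 ± 0.17 (r = -0.66), PAG11, whose other probe differed by -0.44, by 2.45 ± 0.51 and the calcium-binding protein CALB1 by 2.21 ± 0.34. NQO1, not above background in day8, was at least 2.01-fold lower. GATA4 fell by 2.54 ± 0.55 (r = -0.81), PLCH1 by 3.30 ± 0.69 (r = -0.81) and ARPP21 by 2.70 ± 0.61 (r = -0.79). The 5 largest rises all belonged to the co-varying set: ROBO2 (3.83 ± 0.83, r = 0.97), ARSI (3.76 ± 0.84, r = 0.97), APBB3 (3.65 ± 0.84, r = 0.94), ARMC5 (3.61 ± 0.78, r = 0.95) and ITGA7 (3.42 ± 0.69, r = 0.96). So did the water channel AQP3, which rose by 2.50 ± 0.57 (r = 0.92) while its other probe differed by -0.17. HMOX1 (-1.70 ± 0.41, adjusted p = 0.0572), DNMT3B (-1.02 ± 0.24) and POU5F1 (0.98 ± 0.26) did not pass. The oxidative stress list fell by a mean of 0.45 (adjusted p = 3.16e-09, 0.0235 with an estimated correlation) and by 0.51 with the slide as a block. Of its 33 genes 0 rose, 3 fell and 30 did not pass (0 rose and 13 fell adjusted over the list alone). The trophoblast secretory list fell by 0.62 (adjusted p = 7.20e-05, 0.263 with an estimated correlation; 0 rose, 1 fell and 19 did not pass (0 rose and 7 fell adjusted over the list alone)), and glycolysis fell by 0.25 (0.00745, 0.193 with an estimated correlation). X-linked genes rose by 0.27 (4.65e-04, 0.125 with an estimated correlation). In limma's fit 196 features passed, 130 higher and 66 lower in day8, and 79 of the rises were in the co-varying set; 15.6% of all features had groups that did not overlap, where chance gives 10%. With the co-varying set and the 80 features with r under -0.8 left out 81 passed. Centred on the median the split was 64 and 62, and ROBO2, ARSI, APBB3, ARMC5 and AQP3 did not pass. Of the genes named here that passed, SRXN1, GPX4 and CALB1 alone also passed with the mean of a gene's probes. All of them but SRXN1 and CALB1 did not pass whichever of the 6 arrays was left out, GPX4, PAG11, NQO1 and GATA4 among them. No slide held arrays of both groups, and with the slide as a block 1 passed, CALB1, which fell by 3.13 in that fit. The count was 8 without day8 replicate 1, 4 without day8 replicate 2, 2 without day8 replicate 3, 11 without day6+2 replicate 1, 8 without day6+2 replicate 2 and 1 without day6+2 replicate 3, and 0 of the 14 named genes that passed did so whichever array was left out; SRXN1 passed except without day6+2 replicate 3.

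Day8 with day7+1 also compared blastocysts of equal age. The fit in limma called 0 of 34269 features, against 2785 with an unadjusted p under 0.05. Of all features, 12.98% had groups that did not overlap, where chance gives 10%. The smallest p-values of named genes were those of TMEM35 (0.89 ± 0.17), SHISA4 (2.18 ± 0.41, r = 0.96) and LOC100140788 (0.91 ± 0.16), each with an adjusted p = 0.101; GATA4 differed by -2.08 ± 0.55 and DNMT3B by -1.07 ± 0.24. Slide 2 held 2 arrays of each group, and in a fit of those 4 arrays alone 492 features passed, 325 higher and 167 lower in day8. The count was 395 with day6+1 replicate 1 and day7 replicate 1 both out and 1 without day8 replicate 3. The X-linked list rose by a mean of 0.24 (adjusted p = 0.00158, 0.148 with an estimated correlation), 0.29 within slide 2, and the oxidative stress list fell by 0.16 (adjusted p = 0.0142, 0.186 with an estimated correlation). The heat shock list rose by 0.17 (adjusted p = 0.0467, 0.179 with an estimated correlation).

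Day7+1 with day6+2, both of equal age, gave 0 features in limma's fit, against 1584 with an unadjusted p under 0.05, and 9.66% of all features had groups that did not overlap, where chance gives 10%. The smallest p-values of named genes were those of SPIC (1.20 ± 0.24), QSOX2 (-0.97 ± 0.20) and LOC523509 (-1.84 ± 0.39), each with an adjusted p = 0.784. IFNT differed by -1.35 ± 0.42 and did not pass. The oxidative stress list fell by a mean of 0.29 (adjusted p = 4.37e-06, 0.0428 with an estimated correlation), with 0 single genes past the threshold and 0 adjusted over the list alone. Glycolysis fell by 0.23, the trophoblast secretory list by 0.41, heat shock by 0.19 and proteasome by 0.13, and sterol synthesis rose by 0.18 (adjusted p = 0.134, 0.425, 0.125, 0.282 and 0.508 with an estimated correlation). The slide block gave a proteasome mean of 0.06.

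Day7 with day6+1, of equal age as well, gave 0 features in limma's fit, against 1799 with an unadjusted p under 0.05, and 9.66% of all features had groups that did not overlap, where chance gives 10%. The smallest p-values of named genes were those of the linker histone HIST1H1D (1.65 ± 0.25, adjusted p = 0.0635), the desmosome gene DSP and GCLM (-1.24 ± 0.25). The slide block let 1 feature pass, HIST1H1D, at 1.82. The oxidative stress list fell by a mean of 0.24, -0.24 within slide 3 (adjusted p = 5.25e-04, 0.101 with an estimated correlation), sterol synthesis by 0.23, heat shock by 0.26 and the amino acid list by 0.21 (adjusted p = 0.356, 0.0709 and 0.134 with an estimated correlation).

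The linear fit compared a day spent before cavity formation with a day spent after it, at equal age. Per day SRXN1 fell by 0.76 ± 0.14 (adjusted p = 0.0209), HMOX1 by 1.06 ± 0.22, CALB1 by 1.04 ± 0.17 and ASCL2, a trophoblast transcription factor, by 0.85 ± 0.14. NQO1 and PAG11 fell too, with no size given, as neither was above background in day6. HIST1H1D rose by 0.89 ± 0.13 (adjusted p = 0.0121), the cytokine IL6 by 0.79 ± 0.14 and TRIM63 by 0.91 ± 0.19, and REXO4 (1.24 ± 0.26, r = 0.93) and MOBKL2C (0.80 ± 0.16, r = 0.95), both of the co-varying set, rose too. The oxidative stress list fell by 0.23 per day (adjusted p = 1.65e-10, 0.0117 with an estimated correlation; 0 rose, 3 fell and 30 did not pass (0 rose and 12 fell adjusted over the list alone)), and by 0.24 with the slide as a block. The trophoblast secretory list fell by 0.30 and glycolysis by 0.10, and X-linked genes rose by 0.11 and attachment by 0.09 (adjusted p = 0.230, 0.263, 0.250 and 0.125 with an estimated correlation). In limma's fit 65 features passed, 43 higher and 22 lower per day, 8 of the rises in the co-varying set, and 9 passed with the slide as a block. Centred on the median HMOX1, REXO4 and MOBKL2C did not pass, and with the mean of a gene's probes SRXN1, HMOX1, IL6, TRIM63 and REXO4 did not. The count was 43 without day6 replicate 3, 29 without day8 replicate 1, 22 without day8 replicate 2, 3 without day8 replicate 3, 32 without day6+2 replicate 1, 3 without day6+2 replicate 2, 11 without day6+2 replicate 3, 486 without day6+1 replicate 1, 41 without day6+1 replicate 2, 38 without day6+1 replicate 3 and 208 without day7 replicate 2; of the 11 named genes that passed, HIST1H1D passed whichever array was left out.

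**Figure D4:**
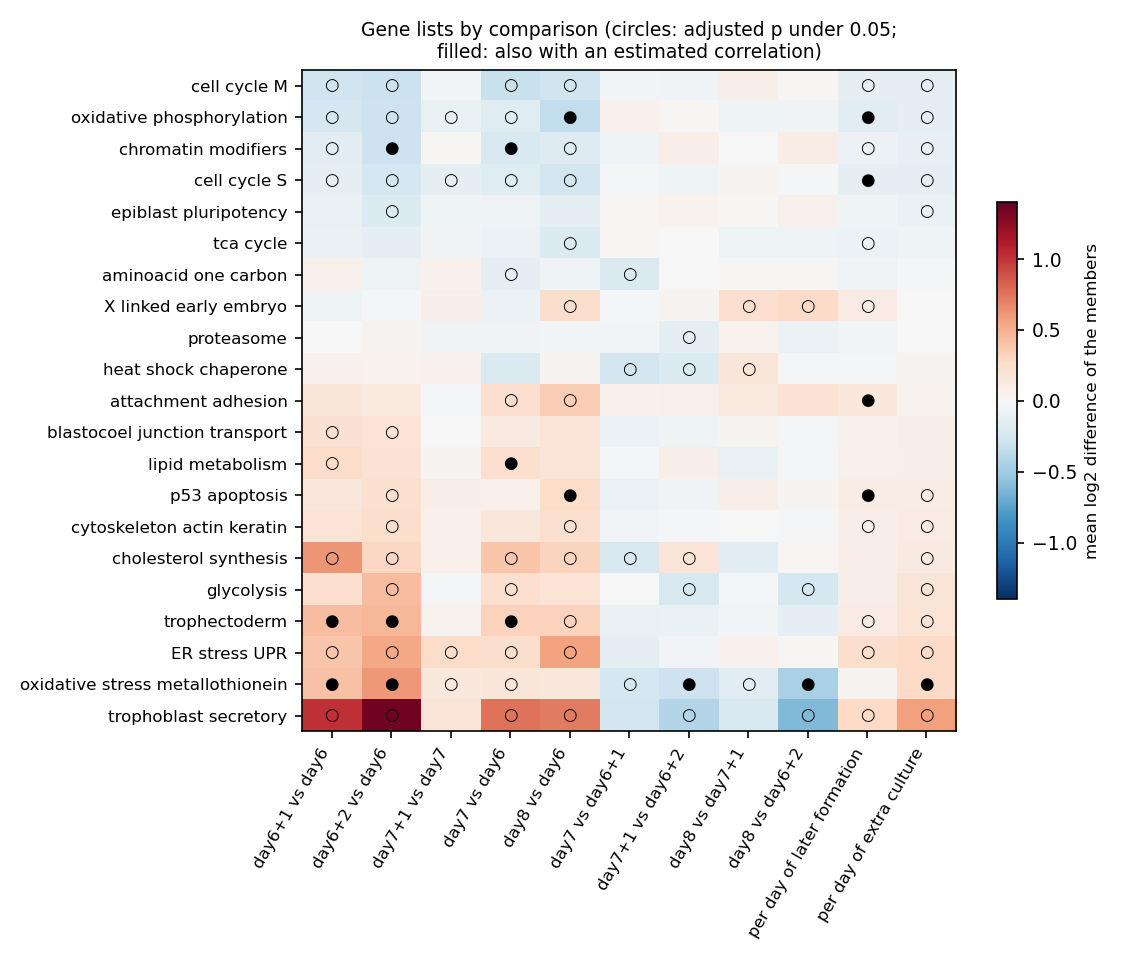
Mean log2 difference of the members of each gene list as colour, for the lists under the threshold in any comparison drawn (9 pairwise comparisons and the trends per day); circles mark an adjusted p under 0.05 in the list test and filled circles those that also pass with an estimated correlation. The trophoblast secretory list has a mean of 1.35 in day6+2 against day6 and -0.62 in day8 against day6+2.

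Over the 403 pairs of 31 lists and 13 comparisons, 111 passed with the preset correlation, 19 of them also with an estimated correlation, and 75 kept direction and threshold with the slide as a block. Of the lists that passed in no comparison, the lowest adjusted p was 0.0992 for the DNA methylation and imprinted list, 0.0737 for the Y-linked list, 0.0601 for the cumulus and granulosa cell list, 0.129 for the fibroblast and kidney epithelial list, 0.0920 for the growth factor list. It was 0.440 for the hypoblast list, 0.0875 for the hypoxia list, 0.157 for the interferon-stimulated list, 0.133 for the oocyte list and 0.193 for the ribosomal protein list. The cumulus, fibroblast and oocyte lists had been included as marks of other cell types and of stored maternal RNA.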

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

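The interaction set the extra day of culture after day 7 against the extra day after day 6, and these results passed its test. Day7+1 against day7 and day6+1 against day6 are its parts. CREB3L2 changed by -1.10 over the extra day after day 6 and by 1.20 after day 7, a difference of 2.30 (adjusted p = 0.0334 in limma). The unnamed probe EMBV3_37916 changed by -0.98 and 1.20, a difference of 2.18 (adjusted p = 0.0334); it was chosen after its values were seen. Over 100 splits of the arrays, with the real one among them, 9 gave as many features as the real 2, and the highest of the others gave 66, so chance cannot be excluded for this count. The splits mixed the arrays of day6, day6+1, day7 and day7+1, so differences between these groups could enter them. What the split with 66 followed was not tested. Both features ended with the slide as a block (0 features, CREB3L2 at 1.86 with an adjusted p = 0.654) and with day6+1 replicate 1 and day7 replicate 1 both out (0 features), so no explanation of them was weighed.

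Among the gene lists, 9 differed between the extra days with the preset correlation. The mean log2 change of the trophoblast secretory list differed by -0.84 (1.02 after day 6 and 0.18 after day 7), of cholesterol synthesis by -0.54 (0.61 and 0.08), of trophectoderm by -0.38 (0.43 and 0.05), of oxidative stress and metallothionein by -0.27 (0.41 and 0.15) and of lipid metabolism by -0.22 (0.26 and 0.04). Those of mitotic cell cycle differed by 0.23 (-0.27 and -0.04), of chromatin modifiers by 0.17 (-0.15 and 0.02), of X-linked genes by 0.17 (-0.07 and 0.09) and of oxidative phosphorylation by 0.13 (-0.23 and -0.11). With an estimated correlation only the trophectoderm list passed (adjusted p = 0.0428). With each array centred on its median the means of mitotic cell cycle, chromatin modifiers, oxidative phosphorylation and X-linked genes changed sign (-0.03, -0.06, -0.13 and -0.04), and the test of oxidative phosphorylation changed direction there and with background subtraction and scaling to the 75th percentile.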

How the results depend on the processing

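The tests with background from the negative controls, with the pair of arrays day6+1 replicate 1 and day7 replicate 1 out, and with the co-varying features out were chosen after the data had been seen. The counts of day6+2 against day6 (1085 to 1533) and of the trend of extra culture (1030 to 1532) stayed within 1.5 times 1229 and 1288 under each alternative other than leaving out a single array, and day7+1 against day6+2 gave 0 throughout. Leaving out the filter moved no count past 1.5 times. No named gene reversed where it had passed. Signal over background limits the low end: genes near the negative controls, such as PAG11 in day6, have only a bound on their fold.

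With the slide as a fixed block the count of features was 1 in day8 against day6, 4 in day7 against day6, 1 in day8 against day6+2, 1 in day7 against day6+1, 29 in day6+1 against day6, 0 in day7+1 against day7, 0 in the interaction, 0 in the trend of later formation and 9 in the trend at equal age. Most calls of the 4 comparisons named next were lost in that fit, while the differences were of similar size: over the features called without the block, the blocked difference was a median of 98.7% of the unblocked one in day8 against day6, 103% in day7 against day6, 105% in day8 against day6+2 and 97.4% in day6+1 against day6, with the same sign in 100%. The median standard error was 1.66, 1.68, 1.69 and 1.42 times as large, from 0.249 to 0.404, 0.250 to 0.416, 0.294 to 0.471 and 0.245 to 0.341, since the groups shared few slides or none. For the called features as a set, these values argue against a slide effect as the whole source of the differences. The precision of the differences within slides stays open. The values do not cover the gene lists. The oxidative phosphorylation mean did shrink with the block in day8 against day6 and in day7 against day6, as given above. With the slide as a random block it was 111 in day8 against day6+2, 1 in day7 against day6+1 and 0 in the interaction. With the replicate number as a block it was 912 in day8 against day6, 187 in day7 against day6, 463 in day8 against day6+2, 3 in day8 against day7+1, 648 in day6+1 against day6, 18 in day7+1 against day7, 51 in the interaction, 175 in the trend of later formation and 135 in the trend at equal age.

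With only the 6 arrays compared the count was 1020 in day8 against day6, 33 in day7 against day6, 799 in day8 against day6+2, 353 in day8 against day7+1 and 0 in day7+1 against day7, and within slide 2 alone it was 492 in day8 against day7+1. With day6+1 replicate 1 and day7 replicate 1 both out it was 1023 in day8 against day6, 62 in day7 against day6, 668 in day8 against day6+2, 395 in day8 against day7+1, 10 in day7+1 against day7, 0 in the interaction, 529 in the trend of later formation and 529 in the trend at equal age. With the co-varying features out (the set of 369 and the 80 with r under -0.8) it was 81 in day8 against day6+2, 1 in day8 against day7+1, 1 in day7 against day6+1, 15 in day7+1 against day7 and 27 in the interaction, with fewer features tested. Background-subtracted and scaled to the 75th percentile the count was 422 in day8 against day6+2, 1 in day8 against day7+1, 1 in day7 against day6+1, 1 in day7+1 against day7, 25 in the interaction and 185 in the trend at equal age. Centred on the median it was 126 in day8 against day6+2, 0 in day7+1 against day7, 4 in the interaction, 16 in the trend of later formation and 35 in the trend at equal age. With the mean of a gene's probes it was 59 in day8 against day6+2 and 37 in the trend at equal age, from the authors' table it was 124 in day8 against day6+2, with the other variance model 86 in day8 against day6+2, 1 in day7 against day6+1, 24 in day7+1 against day7 and 15 in the interaction, and with background from the negative controls 120 in day8 against day6+2, 1 in day7+1 against day7 and 0 in the interaction. The pairs of list and comparison that passed numbered 19 with an estimated correlation and 66 with fry. Except where a smaller set of arrays or features is named, the cause was not tested.

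Leaving out each array in turn gave counts of 42 to 713 in day8 against day6, 10 to 154 in day7 against day6, 1 to 11 in day8 against day6+2, 0 to 1 in day8 against day7+1, 123 to 365 in day6+1 against day6, 695 to 1002 in day6+2 against day6, 0 to 8 in day7+1 against day7, 0 to 70 in the interaction, 1 to 218 in the trend of later formation, 672 to 1391 in the trend of extra culture, 3 to 486 in the trend at equal age and 87 to 117 pairs of list and comparison. Of the 234 values of named genes that passed, 117 did not with the slide as a fixed block. The number was 50 with median centring, 61 with the mean of a gene's probes and 15 with the authors' table. With the slide as a block 54 of 55 stayed in day6+2 against day6 and 55 of 56 in the trend of extra culture. In day6+1 against day6 4 of 33 stayed, and in day8 against day6 1 of 31. Of the 111 pairs of list and comparison, 96 also passed background-subtracted and scaled to the 75th percentile, 93 centred on the median, 109 from the authors' table and 75 with the slide as a block, and 0 passed the other way in the first 3.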

Other observations

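The tests of single probes, of the range within slides and of sex were written after the result had been seen; those of mislabelled arrays, of the slide block, of the position and of other splits were written before.

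The pattern of the co-varying set was high signal on all 3 day8 arrays and on 1 array each of day6+1 and day7. The values argue against the slide: the range of the set's mean was at least 2.37 log2 units within slides 2 and 3, which each held high and low arrays. A candidate explanation is signal of single probes rather than of the gene. The other probes of the same genes differed by a median of 2.02% of the difference of the set's own probes, and 2 of the 97 other probes had r over 0.8. The set's own probes were chosen by r with this component and were each the brightest of their gene. Part of the gap was thus given by the choice. What these probes bind was not examined, as their sequences are not used here. Wrong labels of the 2 arrays stay open. Features with r from -0.8 to 0.8 that parted day8 from the 2 other arrays of the group by over 1 were examined: day7 replicate 1 lay nearer to day8 than to the other day7 arrays for 59.6% of them and day6+1 replicate 1 for 44.4%; the values for the other arrays of these groups were 19.9%, 38.3%, 40.7% and 45.5%. Features within these bounds of r can still follow the first component in part, on which day7 replicate 1 and day6+1 replicate 1 stood with day8. These percentages are thus not independent of the pattern. A difference of late-forming blastocysts, which the design names for day8, stays open too and was not tested, and it would not cover the pair of arrays of other groups.

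XIST, the RNA of the inactive X chromosome, was at 9.74 ± 0.09 (SD, n = 3) in day8 and at group means of 8.84 to 9.14 in the other groups, and the X-linked list was higher in day8 than in day6+2 with the preset correlation but did not pass with an estimated one (adjusted p = 0.125). More female embryos in the day8 samples are a possible explanation. XIST was 0.841 log2 units higher in day8 than in day6+2 (adjusted p = 0.342 in limma), and its SD was 0.713 in day6 and 0.779 in day6+1. The Y-linked list did not pass in any of the 13 comparisons. Of its genes, DDX3Y, EIF1AY and SRY were above the negative controls on 17, 16 and 16 arrays, and TSPY and ZFY on 8 and 6. Their group means were low, at 6.77 to 7.71. With this spread and these low signals the test cannot decide whether the sex of the embryos differed between the groups.

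An axis was drawn from replicates 1 and 2 of day6, at 0, and of day6+2, at 1, over 1215 features, to ask whether the time since the cavity formed or the age since fertilisation set the position of the other groups on it. Day6 replicate 3 lay at 0.137 and day6+2 replicate 3 at 0.859. The mean position was 0.479 ± 0.118 (SD, n = 3) for day7, 0.583 ± 0.186 for day8, 0.705 ± 0.123 for day6+1 and 0.714 ± 0.165 for day7+1. The value for day8 lay between the bounds set for either idea, and so the time since the cavity formed and the age cannot be told apart by this test, whose spread within groups was large.

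The arrays of each comparison were also split in other ways into groups of the same size. For the 9 pairwise comparisons 10 splits exist, too few for a share under 0.05. Day8 against day6 gave 507 features, day7 against day6 99, day8 against day6+2 196, day6+1 against day6 429, day6+2 against day6 1229 and day7+1 against day7 6, each in 1 of 10 splits; the highest other split gave 1 in day8 against day6 and 0 in the remaining 5. Day8 against day7+1, day7+1 against day6+2 and day7 against day6+1 gave 0, which 10 of 10 splits matched or passed; the highest other gave 1, 0 and 307. The split with 307 set day6+1 replicate 1, day7 replicate 1 and day7 replicate 3 against the rest, the 3 of these 6 arrays with the highest mean of the co-varying set. The cause of these 307 calls was not tested. For each trend, 1 of 100 splits gave as many features as the real one. Later formation gave 86 and the highest other 1, extra culture 1288 and 133, and equal age 65 and 2. Each split moved the day of formation and the extra culture of an array as a pair. Later formation was thus not tested with extra culture held fixed. Chance can be excluded for the extra culture count, which was 672 to 1391 with each array left out. For later formation (1 to 218) and equal age (3 to 486) the splits cannot decide, and chance stays open. The splits moved single arrays and did not keep the arrays of a slide together, so they do not exclude the slide. With the slide as a block the count was 0 for later formation, 1477 for extra culture and 9 for equal age. For the list tests 1 of 100 splits gave as many pairs as the real 111, and the highest other gave 78. A total as large was thus rare when all arrays were assigned to the groups at random. This holds for the total and not for any single pair, and 19 of the 111 also passed with an estimated correlation. With the slide as a block 88 pairs passed. A split with 78 shows that the list test also called many pairs in another grouping of the arrays.

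These values were chosen after they were seen. In the reference gene order (ARS-UCD2.0, used for names and order only), 60 genes were listed from IFNT2 to IFNB1, and 22 of them were measured; 13 rose and 0 fell in day6+2 against day6 in limma's fit, with a median of 1.92 over the 22. IFNT rose by 3.56, LOC781778 by 3.66, IFN-tau-c1 by 3.04 and LOC523509 by 2.98. Interferon genes are similar copies, and whether their probes bind each other's transcripts was not examined. LOC513329 and LOC783399, which rose by 4.59 and 4.52 in day6+2 against day6, lay in that order on either side of ZFP37, which differed by -0.04.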
